A study of Mus musculus with 8 samples.

How the data were processed

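Bone marrow RNA of 8 leukaemic mice was measured by RNA sequencing. Libraries were made from total RNA with a SMARTer mRNA kit, per the labels' protocols. The deposited table gives each library's values as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments), per the file headers, rounded to 2 decimals. The aligner and the quantifier are not given in the sources used here. The genome builds GRCm38 and mm10, which are names of the same assembly, come from the submitters' processing notes. FPKM corrects for transcript length and library total but not for differences in composition, and the totals of 606576 to 700238 FPKM show no scaling to a common sum. A few abundant transcripts lower all others: the 10 highest rows held 6.69% to 9.10% of the total. Read counts were not used here, so depth in reads is unknown and no counting interval is given. An exact 0 can be a failed estimate rather than absence, as for Ltb, listed at 0 in 6 of 8 libraries while its neighbour Lta read 94.38 to 258 FPKM, so such genes are described as listed at 0.

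The table has 18020 rows. Of these, 16798 gene numbers matched a symbol in an NCBI RefSeq gene table of assembly GRCm38.p6, whose coordinates are given here, 1119 were unnamed loci with IDs that begin BGI_novel, and 103 others were unmatched. Samples were assigned to groups from the treatment and genotype words in their titles, and replicate numbers follow accession order, so they pair no samples. All 8 libraries differed from one another, with correlations across genes of at most 0.991, and each was counted as 1 replicate.

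Values were transformed to log2(FPKM + 1), so a fold change on this scale understates the change of low genes. Genes with a mean of at least 0.5 FPKM were tested, and 1 gene that the plan kept whatever its mean, 12062 in all, of which 592 were unnamed loci. Group means were fitted to the 8 libraries together with limma (version 3.58.1, R 4.3.3), with an intensity trend in the empirical Bayes moderation, and the 3 differences shared that estimate of the spread. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05, two-sided. Gene lists, 34 in all with 747 of 763 symbols found in the table, were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation was run beside it, as was fry, which compares a list with no other genes and asks in separate tests whether it moves on balance in one direction and whether its genes change in either direction. The lists cover LPS, interferon, replication, DNA repair, B-cell, metabolic and stress genes and markers of other marrow cells.

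Genes were named by a rule. For each main comparison it took the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap in FPKM (10% of genes do so by chance with 3 against 3), and where fewer than 10 passed also the 10 with the smallest p. Immunoglobulin and T-cell receptor segments, mitochondrial genes, pseudogenes and predicted genes were left out of this ranking, and each list added up to 4 members with the smallest p. For the difference of KO_LPS from WT_PBS, genes outside the lists were named only after their values were seen. These choices, the tests and 19 alternatives were fixed before the data were examined. The alternatives were pseudocounts of 0.1 and 5, no filter, a filter at a mean of 5 FPKM, median-ratio scaling, quantile normalization, robust moderation, library weights, fits of only the 2 groups compared, each of the 8 libraries left out, and the other list tests. A further 5 were chosen after seeing the data: removal of each library's trend with GC content and transcript length (loess, longest transcript in GENCODE M21, a value for 93.9% of tested genes), the leading residual component or the first principal component as covariate, tests without unnamed loci, and tests without the 3 libraries with high scores on the first component.

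The fit was tested on simulated data with 200 changed genes among the 12062 genes and the real group sizes, 20 times. The changed genes were drawn only from those with a mean log2(FPKM + 1) of at least 2. Recovery of lower genes was therefore not measured. With independent noise the fit recovered 42.4% of 2-fold and 82.2% of 4-fold changes between WT_LPS and WT_PBS, with 6.45 false calls on average. Between KO_LPS and WT_LPS it recovered 50.0% and 87.8%, with 6.85 false calls. With the leading residual component, which held 64.1% of the residual variance, in the noise, between 107 and 2988 unchanged genes reached an unadjusted p under 0.05 between WT_LPS and WT_PBS and between 74 and 4180 between KO_LPS and WT_LPS. Between KO_LPS and WT_LPS, with independent noise and an unadjusted p under 0.05, camera called 20 of 20 shifted lists of 25 random genes and 2 of 20 unshifted lists. Genes of these lists were not correlated, so false calls for correlated lists were not measured. The correlation of the LPS and Aid differences was set beside 100 simulations of unchanged groups with the shared libraries.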

Results

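Bone marrow RNA was sequenced from 8 leukaemic mice that carried transplanted B cells transformed with BCR-ABL1, the fusion tyrosine kinase that drives a form of B-cell acute lymphoblastic leukaemia. The groups were named for the genotype of the transplanted cells and for the treatment. WT_PBS (n = 2) combined cells with intact Aid and phosphate-buffered saline, the vehicle, and WT_LPS (n = 3) such cells and lipopolysaccharide (LPS), a bacterial cell wall component that activates Toll-like receptors. KO_LPS (n = 3) combined cells without Aid and LPS. The labels word the treatment as that of the cells but give neither time nor route, so whether the cells before transplant or the mice received it is not certain. No library of Aid-deficient cells without LPS was analysed here, so the LPS response of such cells could not be tested. The labels do not say whether the mice of a group received separately transformed cultures, so the p-values measure only the spread between these libraries, which may be technical. Likewise, a difference between WT_LPS and KO_LPS compares the transplanted cells of these mice, whatever set them apart besides Aid.

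Values were FPKM, and they summed to between 606576 in WT_LPS replicate 2 and 700238 in KO_LPS replicate 1, with 15540 to 15894 of 18020 rows above 0. Sequencing depth in reads was unknown. Among low values, the most frequent ratio to WT_PBS replicate 1 ranged from 0.867 to 1.001 in the other libraries, and groups overlapped in it. Only ratios near 1 were searched, so this cannot show whether depths differed by more. Between libraries, the correlation across genes was 0.950 to 0.988 within groups and 0.934 to 0.991 between groups, where genes are not independent replicates. The first principal component held 60.5% of the variance and did not follow the groups. WT_LPS replicate 1, KO_LPS replicate 1 and KO_LPS replicate 2 had scores of 17.4, 34.5 and 50.02, and KO_LPS replicate 3 scored -21.1, between WT_LPS replicate 2 (-30.1) and WT_LPS replicate 3 (-14.2). The libraries were mixtures: the granulocyte protein gene S100a8, chosen after its values were seen, stood at 11250 FPKM in WT_LPS replicate 1 and at 2450 to 6153 FPKM in the other 7, beside B-lineage transcripts. Immunoglobulin V and constant segments were not analysed here, because 0 rows matched a symbol of such a segment.

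**Figure D1:**
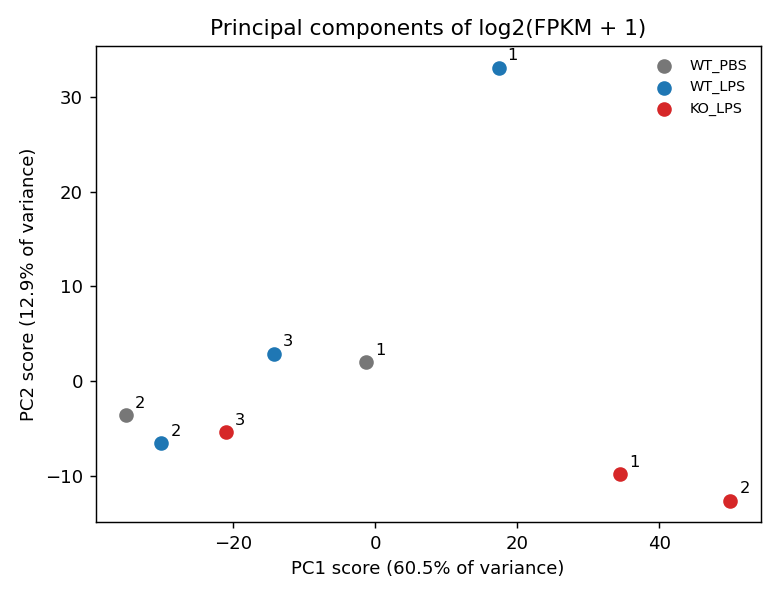
Scores of the 8 libraries on the first and second principal component (arbitrary units, with the share of variance on each axis) of log2(FPKM + 1). Points are libraries, numbered by replicate and coloured by group. KO_LPS replicate 3 lies at -21.1 on the first component and KO_LPS replicates 1 and 2 lie at 34.5 and 50.02.

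The first comparison asked how the marrow transcriptome differed between LPS and vehicle, given to the cells or to the mice, where the transplanted cells had intact Aid. The acute-phase gene Saa3, a classical LPS-induced transcript, was at 64.67 and 36.92 FPKM in WT_PBS and at 185, 288.8 and 366.2 FPKM in WT_LPS. This log2(FPKM + 1) difference of 2.44 ± 0.76 (SE) did not pass (limma, unadjusted p = 0.011, adjusted p = 0.9998). Il1b, encoding the inflammatory cytokine interleukin-1 beta, was at 6.85 ± 1.06 FPKM (SD, n = 2) and 21.2 ± 15.02 (n = 3), and its values overlapped. Among interferon-stimulated genes, 23 of 26 lay below 0, including Gbp7, an interferon-inducible GTPase, at 107 ± 26.03 FPKM in WT_PBS and 74.0 ± 12.2 in WT_LPS. Of 12062 genes, 0 passed, and 142 had an unadjusted p under 0.05 (limma), fewer than the 603 that a uniform distribution gives.

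By the naming rule, the genes with the smallest p were given, none of which passed (limma, adjusted p = 0.9998 for each). Tubb2b, a beta-tubulin, was at 7.42 ± 0.438 FPKM in WT_PBS (SD, n = 2) and 15.9 ± 2.41 in WT_LPS (n = 3). Madcam1, a vessel addressin that binds homing lymphocytes, was at 4.50 ± 0.311 and 1.24 ± 0.599 FPKM, and Sema3a, a secreted guidance protein, at 2.54 ± 0.990 and 0.877 ± 0.0643. The sialyltransferase gene St3gal6 was at 22.5 ± 2.38 and 33.6 ± 1.47 FPKM, and the potassium channel subunit gene Kcnj8 at 3.67 ± 0.339 and 1.53 ± 0.380. Atp6v1e1, a subunit of the vacuolar proton pump, was listed at 0 in WT_PBS replicate 1, at 5.28 FPKM in WT_PBS replicate 2, and at 16.8, 17.02 and 8.67 FPKM in WT_LPS. The remaining 4 were unnamed loci that match no annotated gene, among them BGI_novel_G000851, which was listed at 0 in WT_PBS and at 2.76 to 3.47 FPKM in WT_LPS.

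Of 34 gene lists, 15 stood apart from the other genes between WT_LPS and WT_PBS with a preset correlation, 12 upward and 3 downward (limma's camera, adjusted over the lists). With an estimated correlation 0 passed, the smallest adjusted p being 0.541, and fry passed 0 as well, both for a shift on balance in 1 direction (smallest adjusted p = 0.598) and for change in either direction (smallest adjusted p = 0.917). In every one of the 34 lists, the members that passed numbered 0 over all genes and 0 adjusted over the list alone. Hence each list below is given as a median with members' values.

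The interferon-stimulated list had a median log2 difference of -0.40 over 26 tested members (camera, adjusted p = 1.47e-07; adjusted p = 0.541 with an estimated correlation), and of -0.23 without WT_LPS replicate 1 and -0.63 without WT_LPS replicate 2. Ifit3 and Ifih1, an antiviral effector and an RNA sensor, were at 1.85 ± 0.226 and 1.88 ± 0.240 FPKM in WT_PBS (SD, n = 2), against 0.597 ± 0.310 and 1.04 ± 0.412 in WT_LPS (n = 3). The list of NF-kB and LPS response genes had a median of 0.16 over 25 members, with 14 above 0 (adjusted p = 0.00579; adjusted p = 0.541 with an estimated correlation). Its call ended without WT_PBS replicate 1 (median -0.04, adjusted p = 0.219), without WT_LPS replicate 1 (-0.03, adjusted p = 0.874) and without WT_LPS replicate 2 (0.05, adjusted p = 0.0531), as well as with the first component as covariate (0.09, adjusted p = 0.0524) and with GC and length trends removed (0.16, adjusted p = 0.0550), both chosen after the data were seen. Immediate early and dissociation stress genes had a median of 0.18, with 17 of 19 above 0 (adjusted p = 6.14e-05; adjusted p = 0.541 with an estimated correlation), and 0.11 to 0.32 with 1 library left out. Among them, the transcription factor genes Fos and Junb were at 3.65 ± 1.09 and 39.5 ± 2.09 FPKM in WT_PBS and at 8.39 ± 4.85 and 67.2 ± 30.7 in WT_LPS.

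Replication and energy lists shifted upward by small amounts between WT_PBS and WT_LPS. For DNA replication and the G1/S step the median was 0.11, with 25 of 32 members above 0 (camera, adjusted p = 0.000179; adjusted p = 0.611 with an estimated correlation), and the helicase subunit gene Mcm7 was at 221 ± 11.3 and 270 ± 36.3 FPKM. The G1/S median was 0.05 without WT_LPS replicate 3, 0.07 without WT_PBS replicate 2 and 0.18 with median-ratio scaling. Oxidative phosphorylation had a median of 0.11 with 24 of 27 above 0 (adjusted p = 7.27e-06) and glycolysis 0.10 with 12 of 17 above 0 (adjusted p = 0.00126), each with adjusted p = 0.541 with an estimated correlation. Both calls ended without WT_LPS replicate 1 (adjusted p = 0.123 and 0.0960), and glycolysis also without WT_PBS replicate 1 (median -0.01, adjusted p = 0.818). Cytosolic ribosomal proteins had a median of 0.11 with 23 of 31 above 0 (adjusted p = 0.000341; adjusted p = 0.746 with an estimated correlation), but the direction of the test turned under quantile normalization (adjusted p = 0.851) and without WT_PBS replicate 2 (adjusted p = 0.888), and the call ended without WT_LPS replicate 1 (adjusted p = 0.509). Genes of B cell identity and the pre-B cell receptor had a median of 0.08 with 18 of 27 above 0 (adjusted p = 0.00401; adjusted p = 0.541 with an estimated correlation), with Tcf3, an E-protein transcription factor of B-cell commitment, at 151 ± 6.02 and 180 ± 18.5 FPKM and Pax5, a B-lineage transcription factor, at 137 ± 0.332 and 105 ± 25.02. That call ended under quantile normalization (adjusted p = 0.264) and without WT_PBS replicate 1 (0.01, adjusted p = 0.123). With median-ratio scaling, medians were 0.19 for oxidative phosphorylation, 0.18 for glycolysis, 0.18 for ribosomal proteins and 0.15 for B cell identity. The median over all genes was then 0.01, in place of -0.06. Quantile normalization gave 0.06, 0.07, 0.0171 and 0.04 for these lists.

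Antigen presentation and markers of other marrow cells followed. MHC class I genes had a median of 0.16 with 14 of 16 above 0 (camera, adjusted p = 0.0153; adjusted p = 0.699 with an estimated correlation) and MHC class II genes 0.11 with 9 of 13 above 0 (adjusted p = 0.0350; adjusted p = 0.541 with an estimated correlation). Median-ratio scaling ended the class I call (0.23, adjusted p = 0.05004) and the class II call (adjusted p = 0.0606), as quantile normalization did for class I (adjusted p = 0.141). Without WT_PBS replicate 2 or WT_LPS replicate 1 both calls ended (class I 0.03 and 0.06, adjusted p = 0.635 and 0.138; class II adjusted p = 0.4445 and 0.509), and class II also without WT_LPS replicate 2 (0.13, adjusted p = 0.0525). Stromal and endothelial genes had a median of -0.26, with 15 of 17 below 0 (adjusted p = 0.000279; adjusted p = 0.541 with an estimated correlation), such as the chemokine gene Cxcl12 at 17.1 ± 0.707 FPKM in WT_PBS and 10.3 ± 2.24 in WT_LPS. T-cell genes had a median of 0.12 (adjusted p = 0.000594), NK-cell genes 0.25 over 6 members (adjusted p = 0.0142) and Y-linked genes -0.38 over 4 members (adjusted p = 0.00401), each with adjusted p = 0.541 with an estimated correlation. The T-cell call ended without WT_PBS replicate 2 (adjusted p = 0.0778), and the NK-cell and Y-linked calls without WT_PBS replicate 1 (adjusted p = 0.4475 and 0.664), and the NK-cell call also without WT_LPS replicate 2 (0.18, adjusted p = 0.105). Megakaryocyte and platelet genes had a median of 0.06 (adjusted p = 0.0441; adjusted p = 0.592 with an estimated correlation), a call lost under median-ratio scaling (adjusted p = 0.120), without WT_PBS replicate 1 (adjusted p = 0.664), without WT_LPS replicate 1 (adjusted p = 0.887) and without KO_LPS replicate 1 (adjusted p = 0.0523). The other 19 lists did not pass, with medians from -0.26 (erythroid genes) to 0.04 (p53 targets). They included neutrophil genes (-0.07), which passed downward without WT_LPS replicate 1 (-0.56, adjusted p = 1.12e-05) and upward without WT_LPS replicate 2 (0.14, adjusted p = 0.0253) or 3 (0.23, adjusted p = 0.000274). P53 targets likewise passed upward without WT_PBS replicate 1 (0.25, adjusted p = 1.13e-05) and downward without WT_PBS replicate 2 (-0.29, adjusted p = 0.0233), and in all 6 of the 19 passed with some library left out. The 19 also included TLR4 signalling (-0.09), STAT5 and BCR-ABL1 targets (-0.03), germinal centre and class switching genes (-0.10), known AID off-target loci (0.02), double-strand break repair (-0.07) and the unfolded protein response (-0.07). With 1 library left out, medians ranged from 0.03 to 0.24 for oxidative phosphorylation, -0.01 to 0.28 for glycolysis, 0.01 to 0.14 for B cell identity, 0.04 to 0.29 for MHC class II, 0.04 to 0.22 for T cells, 0.09 to 0.50 for NK cells, -0.03 to 0.24 for megakaryocytes and -0.60 to -0.13 for Y-linked genes. Limited to means of at least 5 FPKM, MHC class I (0.15, adjusted p = 0.123), MHC class II (0.26, adjusted p = 0.210), NK-cell (0.12, adjusted p = 0.307) and stromal (-0.26, adjusted p = 0.123) calls ended. With the first component as covariate, those of MHC class I (0.06, adjusted p = 0.286), MHC class II (0.12, adjusted p = 0.290) and megakaryocytes (0.04, adjusted p = 0.264) ended. Removal of GC and length trends ended MHC class I (0.14, adjusted p = 0.135), MHC class II (0.21, adjusted p = 0.101), megakaryocyte (0.08, adjusted p = 0.245) and Y-linked (-0.13, adjusted p = 0.135) calls. In 7 of the 19, the median, the mean and the test differed in sign.

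The second comparison asked how marrow with cells lacking Aid differed from marrow with intact Aid when both had LPS. Of the genes that passed, 7 were higher in KO_LPS. Iigp1, Igtp, Tgtp1 and Tgtp2 encode immunity-related GTPases that act against intracellular pathogens, and Gbp2 a guanylate-binding protein of the same defence. Iigp1 rose from 3.48 ± 1.30 FPKM in WT_LPS (SD, n = 3) to 32.6 ± 7.39 in KO_LPS (n = 3), Gbp2 from 14.1 ± 1.54 to 94.1 ± 40.1, and Cxcl9, a T-cell-attracting chemokine gene, from 0.923 ± 0.0321 to 9.95 ± 4.07. Tceal9, a gene related to transcription elongation factors, fell from 24.2 ± 2.06 to 8.46 ± 0.928 FPKM, and Fbxw8, a cullin-ligase F-box gene, from 5.85 ± 0.641 to 1.62 ± 0.117. Of 12062 genes, 10 passed, 7 higher and 3 lower (limma, Benjamini-Hochberg), and 687 had an unadjusted p under 0.05 against 603 for a uniform distribution.

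The differences in log2(FPKM + 1) between KO_LPS and WT_LPS were 2.93 ± 0.27 (SE) for Iigp1 (limma, adjusted p = 0.0134), 2.56 ± 0.31 for Gbp2 (adjusted p = 0.0387) and 2.43 ± 0.29 for Cxcl9 (adjusted p = 0.0369). Tgtp2 and Tgtp1, which are near-identical neighbours that could share reads, differed by 2.03 ± 0.26 (adjusted p = 0.0471) and 1.96 ± 0.17 (adjusted p = 0.0134), and Igtp by 1.5004 ± 0.19 (adjusted p = 0.0426). Clec2e, a C-type lectin gene of the NK gene complex, was at 0, 0.14 and 0.06 FPKM in WT_LPS and at 2.24, 3.38 and 3.58 FPKM in KO_LPS (adjusted p = 0.0134). Tceal9 fell by 1.41 on the log2 scale (SE 0.15, adjusted p = 0.0151) and Fbxw8 fell by 1.38 (SE 0.17, adjusted p = 0.0426). The unnamed locus BGI_novel_G000369, also fell: it was listed at 0 in all KO_LPS libraries and at 3.51, 4.71 and 2.3 FPKM in WT_LPS (adjusted p = 0.0138). Each of the 7 higher genes read more in every KO_LPS library than in any of the 5 libraries with intact Aid.

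On GRCm38, Iigp1 spans 60373616 to 60392634 on chromosome 18, Gbp2 142620663 to 142638008 on chromosome 3 and Cxcl9 92321331 to 92328079 on chromosome 5. Tgtp1 (48985329 to 48992246), Tgtp2 (49057196 to 49064212) and Igtp (58199556 to 58207592) lie on chromosome 11, and Clec2e lies on chromosome 6 from 129091816 to 129100903. Tceal9 spans 136245080 to 136247139 on chromosome X, and Fbxw8 118064981 to 118155458 on chromosome 5.

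**Figure D2:**
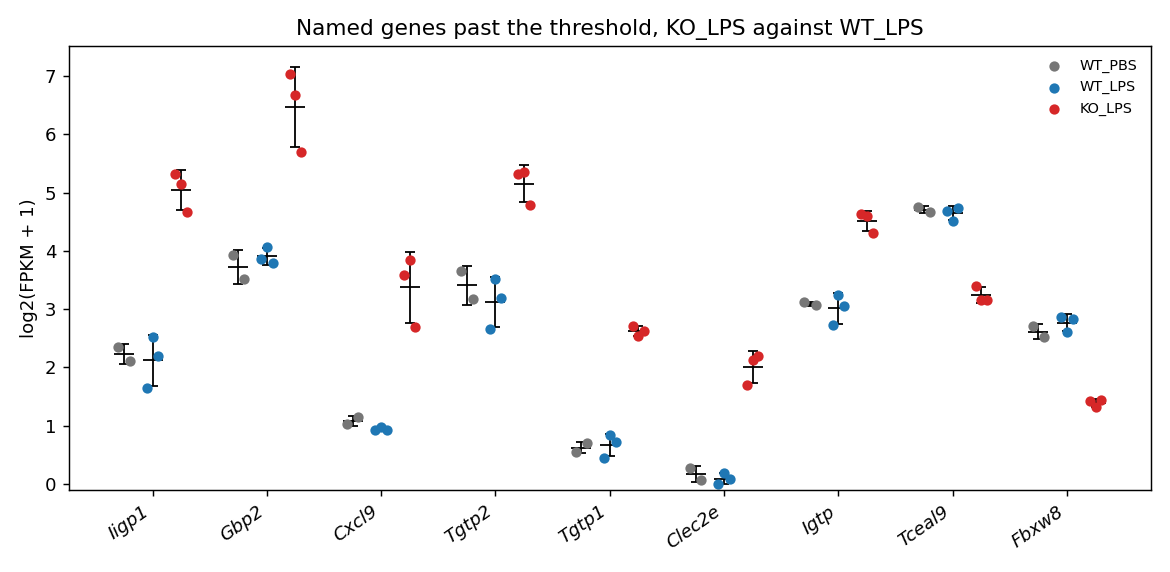
Expression as log2(FPKM + 1) of the 9 annotated genes past the threshold between KO_LPS and WT_LPS. Points are libraries coloured by group, horizontal marks are group means and bars are ± 1 SD (n = 2 for WT_PBS and 3 for the other groups). In the 7 genes at the left, every KO_LPS point lies above every point with intact Aid, while Tceal9 and Fbxw8 lie below.

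The number of calls depended on the libraries that set the spread. With only WT_LPS and KO_LPS in the fit 0 genes passed (584 at an unadjusted p under 0.05), as without either WT_PBS replicate or without WT_LPS replicate 2, whereas without KO_LPS replicate 3 the count was 161. Without the 3 libraries with high scores on the first component, chosen after the data were seen and leaving 1 KO_LPS library, 1 gene passed, which was none of these 10 (their adjusted p was 0.378 to 0.676). Without KO_LPS replicate 2, 1 gene passed, also none of the 10. Tests limited to means of at least 5 FPKM passed 2 genes, and tests with no filter passed 5.

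Of 34 gene lists, 10 stood apart between KO_LPS and WT_LPS with a preset correlation, 6 upward and 4 downward (camera, adjusted over the lists). With an estimated correlation 0 passed (smallest adjusted p = 0.476), and fry passed 0 for a shift on balance in 1 direction (smallest adjusted p = 0.220). Its test of change in either direction, which compares a list with no other genes, passed 2, the interferon-stimulated and the stem and progenitor lists (adjusted p = 0.0346 for each). All 26 tested interferon-stimulated genes lay above 0, with a median of 0.63 (adjusted p = 4.58e-22; adjusted p = 0.476 with an estimated correlation). Of these, 1 rose over all genes (Gbp2) and 14 rose adjusted over the list alone, among them the chemokine gene Cxcl10 at 1.63 ± 0.9998 and 6.91 ± 0.505 FPKM, the nucleic acid sensor gene Zbp1 at 3.58 ± 1.38 and 14.7 ± 5.80, and the ubiquitin-like modifier gene Isg15 at 1.62 ± 1.15 and 7.69 ± 2.64. MHC class I genes had a median of 0.60, with 16 of 16 above 0 (adjusted p = 1.497e-12; adjusted p = 0.687 with an estimated correlation). In that list 0 passed over all genes and 8 rose adjusted over the list alone, including the immunoproteasome subunit gene Psmb9 (89.3 ± 5.55 and 137 ± 20.97 FPKM) and the peptide-loading gene Tapbp (33.4 ± 2.61 and 64.7 ± 24.0). MHC class II genes had a median of 0.45 with 8 of 13 above 0 (adjusted p = 0.00456; adjusted p = 0.687 with an estimated correlation), with 0 passing either way, and H2-Aa at 12.8 ± 5.35 and 56.6 ± 39.9 FPKM. The class II call ended without KO_LPS replicate 1 (0.27, adjusted p = 0.0564), with the first component as covariate (0.19, adjusted p = 0.302) and without the 3 libraries with high scores (0.02, adjusted p = 0.123), where the interferon-stimulated and class I medians were 0.36 and 0.16. By library, the class I median deviation from the mean of all libraries was 0.76 and 0.46 in KO_LPS replicates 1 and 2, -0.09 in KO_LPS replicate 3 and -0.26 to -0.10 in WT_LPS. That of interferon-stimulated genes was 0.37, 0.35 and 0.20 in KO_LPS, -0.70, -0.04 and -0.42 in WT_LPS, and 0.05 and 0.10 in WT_PBS.

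Among growth and energy lists, ribosomal proteins had a median of 0.17 with 31 of 31 above 0 (camera, adjusted p = 5.54e-07), oxidative phosphorylation 0.15 with 23 of 27 above 0 (adjusted p = 9.77e-05) and mitosis 0.12 with 23 of 30 above 0 (adjusted p = 0.00187). Each had adjusted p = 0.687 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. Quantile normalization ended the ribosomal call (0.04, adjusted p = 0.0731), WT_LPS replicate 2 left out ended those for oxidative phosphorylation (adjusted p = 0.200) and mitosis (adjusted p = 0.0885), and KO_LPS replicate 2 left out ended that for mitosis (0.03, adjusted p = 0.219). With 1 library left out the medians ranged from 0.10 to 0.29, 0.04 to 0.25 and 0.03 to 0.21 for the 3 lists. With the first component as covariate the ribosomal median turned (-0.0111, adjusted p = 0.749) and the calls for oxidative phosphorylation (adjusted p = 0.986) and mitosis (adjusted p = 0.218) ended. Without the 3 libraries with high scores the ribosomal median turned too (-0.0238, adjusted p = 0.506) and that for oxidative phosphorylation ended (adjusted p = 0.111). Across the 8 libraries, the ribosomal median followed the score on a first component computed without its members (Pearson r = 0.965, exact permutation p = 0.000422, adjusted p = 0.00873 over 32 lists; Spearman's rho = 0.952, exact permutation p = 0.00114, adjusted p = 0.0183). It did so without the 2 libraries farthest from the median score too (r = 0.966). The component holds most of the variance of these same libraries, so the p-values do not set this list apart from others. Rpl10 was at 238 ± 20.5 FPKM in WT_LPS and 294 ± 10.2 in KO_LPS.

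Lists of granulocyte, platelet and B-lineage genes were placed downward between KO_LPS and WT_LPS with the preset correlation alone. By library, the neutrophil median deviation from the mean of all libraries was 1.21, -0.07 and -0.25 in WT_LPS and -0.81, -1.001 and 0.38 in KO_LPS, so the groups overlapped in it. All 22 neutrophil genes lay below 0, with a median of -0.73 (camera, adjusted p = 1.32e-05; adjusted p = 0.687 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. S100a8 was at 6094 ± 4466 and 3759 ± 1838 FPKM. Without WT_LPS replicate 1, the library with the most S100a8, the median was -0.30 and the call ended (adjusted p = 0.532), and without all 3 libraries with high scores it turned to 0.54. Without KO_LPS replicate 3 it was -1.17. Eosinophil, basophil and mast-cell genes had a median of -0.57 with 11 of 11 below 0 (adjusted p = 0.00509) and megakaryocyte and platelet genes -0.46 with 11 of 11 below 0 (adjusted p = 9.16e-05), each with adjusted p = 0.687 with an estimated correlation. Of these, only Itgb3, an integrin subunit of platelets, fell adjusted over the list alone, from 4.86 ± 0.352 to 2.51 ± 0.602 FPKM, and 0 passed over all genes. Without WT_LPS replicate 1 those medians shrank to -0.33 and -0.25 and both calls ended as well (adjusted p = 0.417 and 0.0815), and the first of them also without KO_LPS replicate 3 (-0.44, adjusted p = 0.0763), limited to means of at least 5 FPKM (adjusted p = 0.243) and without the 3 libraries with high scores (-0.31, adjusted p = 0.0633). B cell identity and pre-B cell receptor genes had a median of -0.21 with 23 of 27 below 0 (adjusted p = 0.00456; adjusted p = 0.687 with an estimated correlation). It was -0.11 without KO_LPS replicate 1, -0.37 without KO_LPS replicate 3, -0.09 with the first component as covariate and -0.06 without the 3 libraries with high scores. In that list 0 passed over all genes and 1 fell adjusted over the list alone, Ikzf3, which encodes the lymphoid regulator Aiolos, at 6.03 ± 2.57 and 1.32 ± 0.720 FPKM.

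The remaining 24 lists did not pass between KO_LPS and WT_LPS, with medians from -0.23 (double-strand break repair) to 0.23 (dendritic cells), though 8 of them passed camera's preset test with some library left out, 6 of these without KO_LPS replicate 3. Monocyte and macrophage genes had a median of 0.17, and adjusted over the list alone Axl, a receptor kinase of phagocytes, rose (1.47 ± 0.289 to 3.13 ± 0.625 FPKM) while Csf1r, the receptor of macrophage growth factor, fell (35.3 ± 5.59 to 21.9 ± 3.08), as did the fibronectin gene Fn1 (36.7 ± 11.9 to 13.1 ± 9.24). In the stem and progenitor list (median -0.08), Ly6a, the interferon-inducible antigen Sca-1, rose adjusted over the list alone (6.07 ± 0.687 to 44.9 ± 27.3 FPKM) and Flt3 and Mycn fell, and 0 of its 8 tested members passed over all genes. In the dendritic-cell list Bst2, an interferon-inducible membrane protein gene, rose adjusted over the list alone and Flt3 fell. The lists of AID partners and mismatch repair (-0.18), known AID off-target loci (-0.03), germinal centre genes (-0.12), p53 targets (0.10), STAT5 and BCR-ABL1 targets (0.05), apoptosis regulators (0.06), NF-kB and LPS response (-0.19), T cells (0.01) and erythroid genes (0.16) did not pass. Among the 8 that did with a library left out, AID partners were at -0.36 (camera, adjusted p = 0.0259) and double-strand break repair at -0.46 (adjusted p = 0.0180) without KO_LPS replicate 3. The NF-kB and LPS response list was at -0.40 without WT_LPS replicate 3 (adjusted p = 0.000678). Erythroid transcripts were uneven: Hbb-bs, an adult beta-globin gene chosen after its values were seen, stood at 385.5, 306.4 and 28.83 FPKM in KO_LPS and at 28.18 to 95.71 FPKM in WT_LPS. In 8 of the 24, the median, the mean and the test differed in sign.

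**Figure D3:**
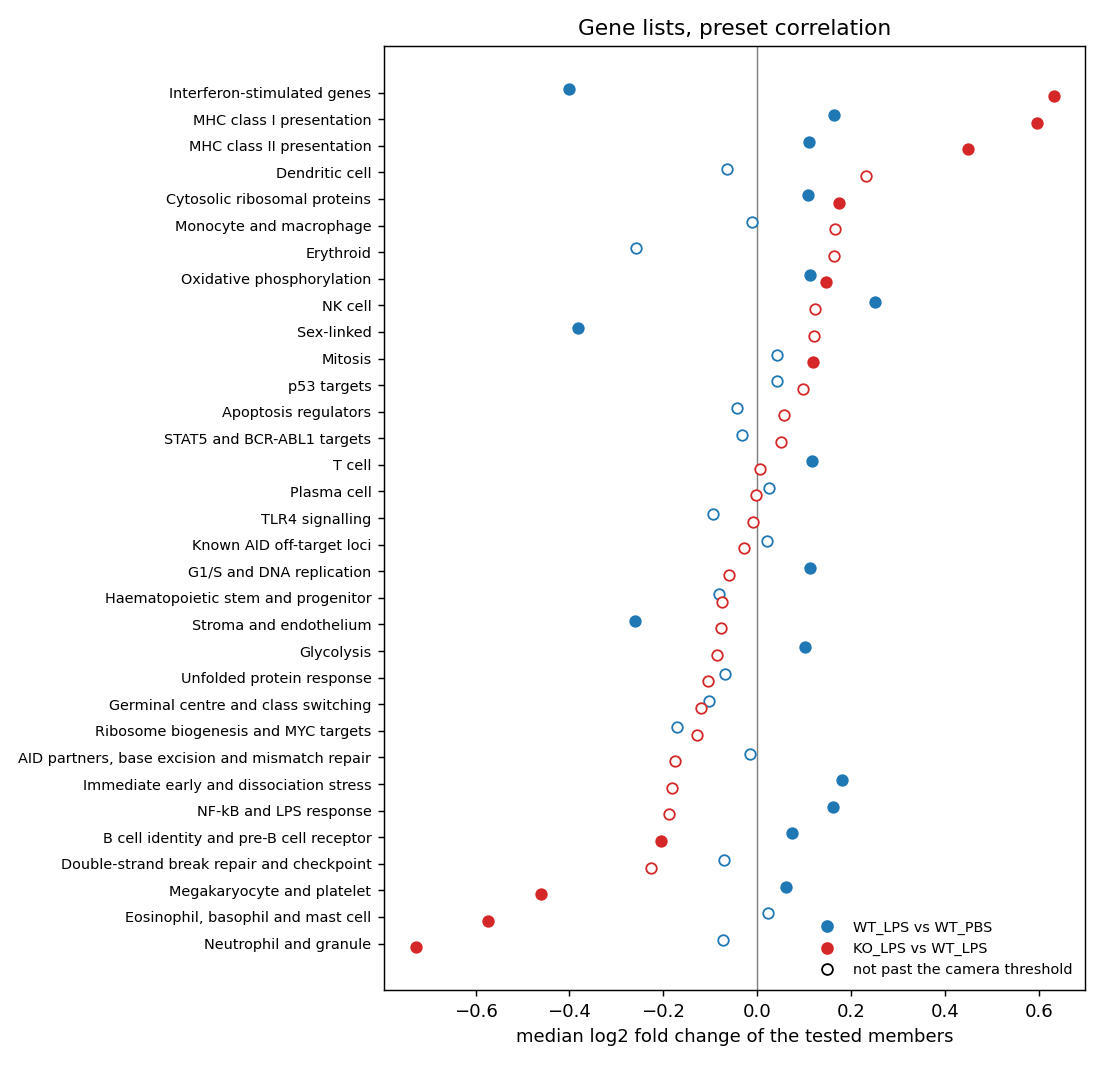
Median log2(FPKM + 1) difference (x axis) of the tested members of gene lists fixed beforehand (y axis), for WT_LPS against WT_PBS in blue and KO_LPS against WT_LPS in red. Filled points passed camera with a preset correlation, and 0 lists passed with an estimated correlation. The interferon-stimulated list lies at -0.40 in blue and 0.63 in red. Both comparisons use the WT_LPS libraries, so opposite signs can arise from these libraries alone.

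A further question was whether Aid loss moved genes against the LPS difference. Across 12062 genes, the differences for LPS and for Aid loss had a correlation of -0.058 and a covariance of -0.00441. As 0 genes passed between WT_LPS and WT_PBS, none could pass in both. The comparisons share the WT_LPS libraries, which alone gave a mean correlation of -0.448 (-0.482 to -0.393) and a mean covariance of -0.0419 (-0.0460 to -0.0358) in 100 simulations of unchanged groups with independent noise. With the libraries' leading residual component in the noise, the simulated covariance averaged -0.0375 and ranged from -0.319 to 0.0622, which holds the observed value. Genes are not independent replicates, and no overall reversal was detectable.

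Between KO_LPS and WT_PBS, which differ in both genotype and treatment, 6 of 12062 genes passed, 4 higher and 2 lower (limma), and 807 had an unadjusted p under 0.05. Named after their values were seen, Tgtp1, Iigp1, Clec2e and St3gal6 were higher and Tceal9 and Gldc, the glycine-cleavage decarboxylase gene, lower. St3gal6 was at 20.84 and 24.2 FPKM in WT_PBS and at 51.1 to 64.05 in KO_LPS (log2 difference 1.33 ± 0.15, adjusted p = 0.0276), and Gldc at 4.22 and 8.88 against 0.07 to 0.13 FPKM (adjusted p = 0.0443). Of 34 lists 8 passed with a preset correlation and 0 with an estimated one (smallest adjusted p = 0.663). Fry passed 0 for a shift in 1 direction, and 1 for change in either direction, the stem and progenitor list (adjusted p = 0.0356). Of the 26 lists that did not pass camera's preset test, 14 did with some library left out. MHC class I (median 0.76), MHC class II (0.36), interferon-stimulated genes (0.20), oxidative phosphorylation (0.28), ribosomal proteins (0.22) and mitosis (0.12) lay upward, and neutrophil genes (-0.81) and stroma (-0.32) downward, each with adjusted p = 0.663 to 0.733 with an estimated correlation. Adjusted over the list alone, 7 MHC class I, 2 MHC class II and 3 interferon-stimulated genes rose, and 0 members of these 8 lists passed over all genes. Quantile normalization ended the ribosomal (adjusted p = 0.255) and stroma (-0.14, adjusted p = 0.161) calls. The neutrophil call ended without WT_PBS replicate 2 (-0.67, adjusted p = 0.0588), and the stroma call without any of 5 libraries (adjusted p of 0.0718 to 0.332), with either other pseudocount (adjusted p = 0.0603 and 0.0545), at means of at least 5 FPKM (adjusted p = 0.485) and with GC and length trends removed (adjusted p = 0.0965). Without the 3 libraries with high scores, the ribosomal call ended (adjusted p = 0.977) and the neutrophil median turned to 0.0462. The medians there were 0.22 for MHC class I, 0.07 for MHC class II (adjusted p = 0.0406), 0.09 for interferon-stimulated genes (adjusted p = 0.0107) and 0.13 for oxidative phosphorylation (adjusted p = 0.00610), smaller but still past the threshold. With the first component as covariate these 4 were 0.43, 0.13, 0.33 and 0.09, still past, and the first component as covariate ended the ribosomal call too (adjusted p = 0.253). With 1 library left out, medians ranged from 0.02 to 0.21 for mitosis, 0.17 to 0.63 for MHC class II, 0.15 to 0.32 for interferon-stimulated genes, 0.13 to 0.35 for ribosomal proteins, -1.31 to -0.57 for neutrophil genes and -0.47 to -0.15 for stroma. The median difference over all genes was -0.12 in this comparison and 0.01 after median-ratio scaling. Under that scaling 3 genes passed, all higher, and under quantile normalization 10 passed, 7 higher and 3 lower.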

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

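The removal of GC and length trends, the 2 covariates, the tests without unnamed loci and those without the 3 libraries with high scores on the first component were chosen after the data were seen. Over the alternatives, list results kept direction and side of the threshold in 2172 cases, against 158 weaker, 89 stronger and 26 reversed, and named genes did so in 5802 cases, against 100 weaker, 161 stronger and 1 reversed. Most lists and named genes had not passed and had no call to lose, so these tallies do not measure how stable the calls were. All weaker cases of named genes were lost calls of the 10 genes that passed between KO_LPS and WT_LPS. Iigp1 stayed past the threshold in 14 of 22 alternatives (log2 difference 2.14 to 3.23), Tceal9 in 12 of 22 (-1.51 to -1.12), Gbp2 in 10 of 22 (1.77 to 3.19), Fbxw8 in 9 of 21 (-1.78 to -0.71) and Cxcl9 in 8 of 21 (1.30 to 3.20). The other 5 genes did so in 10 to 14 alternatives. The pseudocounts of 0.1 and 5 moved low genes most, such as Clec2e (4.31 and 0.67), Tgtp1 (2.97 and 0.87) and BGI_novel_G000369 (-5.12 and -0.76). Fits that leave a group with 1 library assume that it varies like the others. Depth in reads was unknown, so values near the floor have no counting interval. No paired analysis was possible because the labels carry no replicate numbers, and those used here follow accession order. Except where fewer libraries or genes were tested, the cause was not tested.

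Genes past the threshold between WT_LPS and WT_PBS numbered 0 in all alternatives (142 at an unadjusted p under 0.05 as reported, limma) but without 1 library, where they ranged from 0 to 2. Between KO_LPS and WT_LPS, in place of 10, they numbered 5 with no filter, 2 with means of at least 5 FPKM, 0 with only the 2 groups compared (584 at an unadjusted p under 0.05) and 0 to 161 with 1 library left out. They numbered 495 with the leading residual component as covariate, which uses the residuals and so understates the spread, 16 with the first component as covariate, and 1, none of the 10, without the 3 high libraries. With median-ratio scaling 12 passed, 7 higher and 5 lower. Library weights passed 8867, but their estimate did not settle: WT_LPS replicate 3 had a weight of 58.02 and the others 0.162 to 6.97. Between KO_LPS and WT_PBS, in place of 6, genes numbered 0 with no filter, 3 with means of at least 5 FPKM, 3 with median-ratio scaling, 10 with quantile normalization, 2988 with library weights and 0 with only the 2 groups (620 at an unadjusted p under 0.05). They numbered 1284 with the residual component, 1, none of the 6, without the 3 high libraries and 0 to 124 with 1 library left out.

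Lists past the threshold numbered 0 in each comparison with camera's estimated correlation, and 0 in each with fry's test of a shift in 1 direction. Its test of change in either direction passed 0 between WT_LPS and WT_PBS, 2 between KO_LPS and WT_LPS and 1 between KO_LPS and WT_PBS. Between KO_LPS and WT_PBS, in place of 8, they numbered 16 with the first component as covariate, 19 without the 3 high libraries and 7 to 14 with 1 library left out.

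List medians whose test turned are given here. Between WT_LPS and WT_PBS these were ribosomal proteins under quantile normalization (0.0171) and without WT_PBS replicate 2 (0.0167; 0.0167 to 0.19 over the libraries left out), p53 targets without WT_PBS replicate 2 (-0.29; -0.29 to 0.25), NF-kB and LPS response with library weights (-0.23), and neutrophil genes with library weights (-0.63), without WT_LPS replicate 1 (-0.56; -0.56 to 0.24) and without the 3 high libraries (-0.56). Between KO_LPS and WT_LPS, library weights turned immediate early genes (0.26) and the single gene Gzma (-0.34). The first component as covariate turned p53 targets (-0.21), ribosomal proteins (-0.0111) and ribosome biogenesis (0.15). Without the 3 high libraries, G1/S (0.17), AID off-target loci (-0.0607), STAT5 targets (-0.12), ribosomal proteins (-0.0238), neutrophil (0.54) and erythroid genes (-0.14) turned. Between KO_LPS and WT_PBS, the first component as covariate turned p53 targets (-0.26) and ribosome biogenesis (0.11). Without the 3 high libraries, AID partners (0.17), double-strand break repair (0.0814), p53 targets (-0.16), STAT5 targets (-0.14), immediate early (-0.35), neutrophil (0.0462) and erythroid genes (-0.38) turned there.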

Other observations

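The tests in this part were chosen after the results were seen, except camera with an estimated correlation, which was planned. Double-strand break repair genes, which include those of homologous recombination, had lower medians at higher scores on the first component: their median followed the score of the 8 libraries with Pearson r = -0.958 (exact permutation p = 0.000546, adjusted p = 0.00873 over 32 lists; Spearman's rho = -0.881, exact permutation p = 0.00724, adjusted p = 0.0386), and r = -0.863 without the 2 libraries farthest from the median score. Ribosome biogenesis and MYC targets followed it with r = -0.915 (exact permutation p = 0.00243, adjusted p = 0.0156; rho = -0.952, exact permutation p = 0.00114, adjusted p = 0.0183), and r = -0.969 without those 2 libraries. For each list the score was computed without its members, but from the same libraries. That component holds 60.5% of the variance, so a list can follow it without being set apart. AID partners (r = -0.922) and oxidative phosphorylation (r = 0.919) followed it too, while NF-kB and LPS response did not (r = 0.00901). The p-values, here and for B cell identity genes below, compare no list with other genes.

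Of the 7 genes higher in KO_LPS than in WT_LPS, several are known to be interferon-inducible, a grouping made after they were seen; the interferon-stimulated list fixed beforehand had an adjusted p = 0.476 in camera with an estimated correlation. With the score on the first component as covariate, the median log2 difference of the 7 genes that rose was 2.05 (SD over genes 0.416), against 2.03 (SD 0.476) without it. Of the 7, 6 still passed (Tgtp2 had limma's adjusted p = 0.0595). The genes were picked for differing between these same groups, and the component was computed with them. Hence this cannot decide whether the component accounts for them. Without the 3 libraries with high scores, which leaves 1 KO_LPS library, their differences were 1.16 to 2.31. More monocytes and macrophages in proportion would move their markers alike, and these had a median of 0.17 with an SD of 0.737, with 14 above 0 and 9 below. The genes that rose, with a median of 2.03, were picked for rising, so markers not so picked would tend to lie lower anyway. Hence the gap between the 2 medians cannot decide whether more such cells account for these genes. An interferon response in the marrow of mice that carry Aid-deficient cells is a hypothesis, and loss of Aid, a difference between transformed cultures, an infection shared by the KO_LPS mice and a few strongly activated cells stay open, untested.

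The 6 LPS libraries have only 10 splits into 3 and 3, too few for a share under 0.05. Of the 10, 2 gave at least 10 genes: the real split itself, with 10, and 1 other, with 3283. That other split set WT_LPS replicate 1 and KO_LPS replicates 1 and 2 against WT_LPS replicates 2 and 3 and KO_LPS replicate 3, which follows the first component and points to a structure of the samples.

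For that first component, removal of each library's trend with GC content and length left 61.5% of the variance in it, against 60.5% before, which argues against such a trend as its source. A smaller share of leukaemia cells stays open: B cell identity genes had a median slope of -0.23 log2 per SD of the score (SD over genes 0.319; r = -0.896, exact permutation p = 0.0034, adjusted p = 0.0181; rho = -0.810, exact permutation p = 0.0218, adjusted p = 0.0812; r = -0.840 without the 2 farthest libraries). Markers of other marrow cells had no common direction: slopes were 0.13 (SD 0.686) for erythroid, 0.10 (0.233) for dendritic, 0.02 (0.406) for monocyte, 0.0042 (0.317) for eosinophil, -0.01 (0.160) for T-cell, -0.025 (0.148) for stromal, -0.07 (0.156) for megakaryocyte and -0.20 (0.384; 1 of 6 genes above 0) for NK-cell markers. The erythroid median rose with the score, though only 7 of 12 genes had slopes above 0. Its relation had r = 0.796 (exact permutation p = 0.0210, adjusted p = 0.0747) and rho = 0.833 (exact permutation p = 0.0154, adjusted p = 0.0703). Without the 2 farthest libraries r was 0.697. Neutrophil markers, which would go up with such a share, had a median slope of -0.345 (SD over 22 genes 0.286), but their relation to the score was weak (r = -0.497, exact permutation p = 0.212, adjusted p = 0.376; rho = -0.524, exact permutation p = 0.197, adjusted p = 0.393) and turned without the 2 farthest libraries (r = 0.511). RNA handling, the state of the leukaemia cells and the stage of disease at collection were not tested and stay open, and the design gives no biological factor that follows the score. The numbers in the sample titles, looked at after the scores were seen, did split with it. Libraries titled X1, X2, X5 and X6 scored -1.30 to 50.02, and those titled X7, X8, X40 and X100 scored -35.1 to -14.2. What these numbers stand for is not given in the labels.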
